A study of Solanum lycopersicum with 12 samples.

How the data were processed

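Leaf RNA of tomato (Solanum lycopersicum) wild type and jmj4 mutant plants was sequenced after 12 h at 25 or 4 degrees C, with 3 libraries in each of 4 groups. Per the labels' protocols, total RNA was extracted with a commercial kit and libraries were made with an NEB RNA library kit. The authors deposited 1 table of raw read counts per gene, with 1 column for each of the 12 libraries and no normalization. The submitters' processing notes name HISAT2 2.0.5 and featureCounts 1.5.0-p3. Their settings, including strand and the treatment of reads with several matches, are not given in the sources used here. Counts of overlapping, antisense or near-identical genes can therefore hold each other's reads. Chromosome names in the table carry the build SL4.0, and coordinates are those of the table. The wild-type 25 degree columns of replicates 2 and 3 are spelled with 1 wrong character in the table and were matched to the only titles they could stand for. Gene names are the descriptions in the count table; symbols such as LOXD, AOS1 or MYC2 come from the gene lists fixed beforehand.

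Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16: TMM scaling, a filter on low counts (filterByExpr by group, which kept 20154 of 34609 entries, 534 of the latter being unannotated transcribed units), 1 coefficient per group over all 12 libraries, and the 2-sided quasi-likelihood test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. The 5 comparisons were cold in wild type, cold in jmj4, jmj4 against wild type at 25 and at 4 degrees, and their interaction. CPM values use TMM-scaled library sizes, except the sums over chromosome 0 models, which use total counts. Principal components used log2 CPM with a prior count of 2. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 31 lists and 5 comparisons together (155 tests), and again with an estimated correlation. Library totals of 14285693 to 18119181 counts set the precision: 3 counts over a group, the floor used for genes at 0, correspond to 0.0516 to 0.0714 CPM.

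The design, tests, gene lists and alternatives were fixed before the data were examined. The 32 lists covered jasmonate biosynthesis, signalling and defence, CBF and DREB factors, cold-regulated proteins, sugar and starch breakdown, fatty acid desaturases, photosystem and Calvin cycle proteins, abscisic acid, gibberellin, auxin, ethylene, salicylic acid, heat shock proteins, WRKY and NAC factors, the circadian clock, JmjC demethylases, histone methyltransferases, BEL1-like factors, core histones, cyclins, ribosomal proteins, flavonoid synthesis, antioxidant enzymes, senescence, markers of trichome, vascular, guard and root cells, and organelle-encoded genes. The last list matched 0 entries and was not tested. Genes were named by rule: per comparison the 8 highest and 8 lowest fold changes with adjusted p under 0.05, a mean CPM of at least 10 and no overlap of libraries; up to 4 members of each list by adjusted p; and the JmjC, BEL1-like, jasmonate and CBF genes. Genes outside that rule were chosen after their values were seen: the on and off genes, the sterol enzymes, the plastid-type models of chromosome 0 and 4 of the interaction genes (Solyc01g105450, Solyc06g083900, Solyc12g096780 and Solyc02g071620).

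Alternatives were RLE, upper quartile and library size scaling, no or a stricter low-count filter (at least 1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, a fold minimum of 1.5, rotation tests (fry) for lists, and each library left out in turn. Replicate numbers come from the sample titles. The scripts were tested on simulated counts for 19928 genes. Changes were placed only in genes above a minimum mean CPM, so the recovery does not cover genes at low counts. For jmj4 at 4 degrees 92% of 2-fold and 100% of 4-fold changes were recovered with 16 false among 208 calls. For the interaction 56% and 100% were recovered with 12 false among 168 calls. Figures were drawn with matplotlib 3.10.9.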

Results

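RNA was sequenced from tomato leaves of wild type and of a jmj4 mutant, a line named for the JmjC-type histone demethylase JMJ4, after 12 h at 25 or 4 degrees C. The design had 4 groups of 3 libraries, 12 libraries in all. The series title places the work around JMJ4, its interaction with the homeodomain factor BLH3, and jasmonate synthesis in the cold. Total counts per library ran from 14285693 to 18119181, and 20154 of the 34609 annotated genes and transcribed units had enough counts to be tested. Unless stated otherwise, levels are given as CPM (counts scaled to TMM-adjusted library size), mean ± SD, with n = 3 in every group. The labels do not say that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical.

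Libraries separated first by temperature. The first principal component held 73.4% of the variance and split the 25 degree from the 4 degree libraries; the second held 6.0% and split wild type from jmj4. Correlations between libraries of 1 group lay between 0.9725 and 0.9857. On the third component, with 4.9% of the variance, wild type 25 degree replicate 3 and jmj4 4 degree replicate 1 lay lowest, at -34.6 and -34.5. At its other end lay wild type 25 degree replicate 2 and jmj4 25 degree replicate 3, at 31.5 and 25.5. Replicate 1 of jmj4 at 4 degrees also lay at 63.7 on the first component, where the other 4 degree libraries lay between 77.4 and 83.8.

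The labels name JMJ4 without a gene identifier, so the list of JmjC demethylases was examined in its place. Of its 49 entries 26 had enough counts to be tested, and JMJ4 may be among the others. The list also took LSD1-like genes by description, and 19 tested members remained without them. None of the 26 tested members differed between genotypes at 25 degrees, at 4 degrees or in the interaction. This was a count of 0 by edgeR, DESeq2 and limma-voom alike, with 3, 4 and 2 members at an unadjusted p under 0.05 in edgeR. Fold changes of jmj4 against wild type ranged from -0.45 to 1 (log2) at 25 degrees and from -0.52 to 0.57 at 4 degrees. The transcript levels therefore gave no check of the genotype labels. Genes described as BEL1-like homeodomain protein 3 (Solyc01g007070) and bell-like homeodomain protein 3 (Solyc08g081400), the nearest descriptions to BLH3, had genotype effects of -0.40 ± 0.15 (log2, SE; adjusted p = 0.328) and 0.23 ± 0.19 (adjusted p = 0.787) at 4 degrees. In the list of BEL1-like and KNOX factors, 0 of 13 members differed by genotype at either temperature with edgeR, DESeq2 or limma-voom; 3 had an unadjusted p under 0.05 at each temperature.

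What did cold do in wild type? Genes of jasmonate synthesis and signalling rose strongly. LOXD (Solyc03g122340, lipoxygenase D, which oxygenates linolenic acid at the start of jasmonate synthesis; chromosome 3, 64655810 to 64660384) went from 19.0 ± 1.04 to 421 ± 71.2 CPM. AOS1 (Solyc04g079730, allene oxide synthase, the next enzyme; chromosome 4, 62071672 to 62073276) went from 0.278 ± 0.197 to 228 ± 65.3, and AOC (Solyc02g085730, allene oxide cyclase; chromosome 2, 46544464 to 46545942) from 61.4 ± 3.3 to 188 ± 29.1. The 3 genes described as Jasmonate ZIM domain protein f, a family of repressors of the jasmonate response, were near 0 at 25 degrees and reached 58.8 ± 19.7 (Solyc08g036640), 12.2 ± 2.93 (Solyc08g036660) and 4.58 ± 1.67 (Solyc08g036620) at 4 degrees. Their near-identical descriptions leave open how reads were shared among them. The gene listed beforehand as MYC2 (Solyc08g076930, described in the count table as jasmonic acid 3), a master regulator of jasmonate responses, rose from 56.9 ± 0.818 to 241 ± 16.6.

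In the list of jasmonate biosynthesis genes, 9 of 23 tested members rose and 1 fell in the cold in wild type, with the same counts when adjusted over the list alone (camera adjusted p = 0.00111; adjusted p = 0.351 with an estimated correlation). In the list of jasmonate catabolism and signalling, 12 of 17 rose and 0 fell, and 12 and 1 adjusted over the list alone (adjusted p = 4.73e-13; adjusted p = 0.165 with an estimated correlation). Among jasmonate-responsive defence proteins, 30 of 59 rose and 6 fell, and 32 and 6 adjusted over the list alone (adjusted p = 0.00111; 0.592 as the adjusted p with an estimated correlation). Leucine aminopeptidase A1 (Solyc12g010020) rose from 0.433 ± 0.289 to 42.8 ± 17 CPM. No list call in any comparison held with an estimated correlation, for the lists fixed before the data were examined.

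Known cold and clock genes moved too. The dehydrin ci7 (Solyc04g082200), a protective protein of dehydrated cells, rose from 37.7 ± 3.79 to 449 ± 33.3 CPM, and EARLY RESPONSIVE TO DEHYDRATION 15 (Solyc10g079820) from 87.7 ± 19.2 to 821 ± 36.5. Of the cold-regulated and dehydrin proteins 22 of 75 rose and 15 fell, and 22 and 16 adjusted over the list alone (adjusted p = 0.358). CBF1 (Solyc03g026280), a transcription factor of the early cold response, was 4.70 ± 0.805 at 25 degrees and 9.24 ± 1.76 at 4 degrees (log2 fold change 0.98, adjusted p = 0.00331). CBF2 (Solyc03g124110) did not pass the test (-1.18, adjusted p = 0.0794), and CBF3 had 0 to 6 counts per library and was not tested. Of 10 CBF and DREB factors 6 rose and 1 fell, and 6 and 2 adjusted over the list alone (adjusted p = 0.0561). The clock genes APRR9 (Solyc03g081240), Adagio-like protein 1 (Solyc01g005300) and GIGANTEA (Solyc12g056650) reached 329 ± 21.7, 203 ± 5.5 and 97.5 ± 1.07 CPM, from 0.323 ± 0.28, 0.386 ± 0.341 and 24.0 ± 3.35. The circadian clock list had 21 of 47 members higher and 9 lower, in both adjustments (adjusted p = 0.000111; adjusted p = 0.481 with an estimated correlation). That list also took efflux carriers by name; without them 15 of 29 rose and 6 fell, with 16 and 7 adjusted over the list alone (adjusted p = 2.59e-06; adjusted p = 0.302 with an estimated correlation). Time of day at sampling is not given in the sources used here.

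Several transcription factor families and hormone genes shifted. In WRKY factors 33 of 52 members rose and 7 fell (adjusted p = 2.87e-10; adjusted p = 0.337 with an estimated correlation), and in NAC factors 22 of 48 rose and 5 fell (adjusted p = 1.54e-07; adjusted p = 0.165 with an estimated correlation), each with the same counts adjusted over the list alone. The genes described as NAC domain protein AY498713 (Solyc04g009440) and NAC domain-containing protein 86 (Solyc03g080090) reached 712 ± 86.1 and 648 ± 19.6 CPM, from 3.08 ± 0.616 and 47.3 ± 3.09. Of 95 genes of abscisic acid synthesis and signalling 45 rose and 14 fell, 46 and 16 adjusted over the list alone (adjusted p = 0.000313; adjusted p = 0.466 with an estimated correlation). The abscisic acid receptor PYL5 (Solyc10g085310) rose from 7.66 ± 1.59 to 113 ± 7.67. Ethylene synthesis and ERF genes rose in 40 of 95 cases and fell in 11, 44 and 11 adjusted over the list alone (adjusted p = 0.000525; adjusted p = 0.431 with an estimated correlation). Gibberellin 2-oxidase 3 (Solyc01g079200), which inactivates gibberellin, reached 28.5 ± 4.38 from 0.0513 ± 0.0888, and gibberellin 20-oxidase-1 (Solyc03g006880), which makes it, fell from 62.9 ± 9.94 to 12.7 ± 0.738. The gibberellin list as a whole had 6 of 27 higher and 9 lower, 8 and 10 adjusted over the list alone (adjusted p = 0.87). The gene described as dwarf (Solyc02g089160) fell from 12.9 ± 2.37 to 2 ± 0.639, and TCP transcription factor 16 (Solyc03g116320) from 16.4 ± 1.35 to 2.10 ± 0.246.

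Other fixed lists had no camera call in wild type, with members higher and lower over all genes, then adjusted over the list alone, as follows. Auxin response genes had 28 higher and 36 lower of 107, then 30 and 39 (adjusted p = 0.522). Heat shock proteins had 40 and 47 of 195, then 41 and 47 (0.776), and salicylic acid and pathogenesis-related genes 20 and 15 of 69 in both (0.643), a list that also took LPR1, CPR1, XPR1 and ZPR1 genes by name. Cyclins and replication genes had 9 and 27 of 78, then 9 and 28 (0.0896). Cytosolic ribosomal proteins had 40 and 7 of 198, then 23 and 6 (0.54). Antioxidant enzymes had 27 and 5 of 85, then 26 and 5 (0.154). Raffinose, trehalose and starch breakdown had 10 and 6 of 28 (0.143) and fatty acid desaturases 9 and 5 of 23 (0.559), in both adjustments. Calvin cycle genes had 2 and 2 of 16, then 2 and 1 (0.738), and flavonoid synthesis 4 and 2 of 24 in both (0.955). JmjC demethylases had 4 and 5 of 26 (0.776) and BEL1-like and KNOX factors 3 and 3 of 13 (0.738), in both. Histone methyltransferases and Polycomb genes had 6 and 12 of 52, then 6 and 10 (0.559). Core histones had 4 and 9 of 56, then 4 and 6 (0.522). Markers of other leaf or plant cell types had no camera call either: glandular trichome 3 and 1 of 20 (0.768), vascular and cell wall 12 and 20 of 58, then 12 and 21 (0.54), guard cell 2 and 3 of 10, then 4 and 3 (0.738), and root 3 and 4 of 14, then 4 and 5 (0.854). Senescence and autophagy had 11 and 3 of 43, then 8 and 3 (0.969). Fry, which does not compare a list with other genes, passed 8 lists without a camera call in wild type, all shifted up: CBF factors, cold-regulated proteins, raffinose and starch breakdown, desaturases, gibberellin, salicylic acid, antioxidant enzymes and guard cell markers. Among the JmjC genes, the jumonji-type Solyc08g076390 rose from 20.9 ± 2.01 to 97.6 ± 7.04 CPM and the LSD1-like Solyc02g081390 from 11.9 ± 2.49 to 102 ± 6.27. Without the LSD1-like genes 3 of 19 JmjC genes rose and 2 fell in the cold in wild type, in both adjustments (adjusted p = 0.736).

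A block of chromosome 0 gene models, taken by a shared identifier prefix and called plastid-type for its products, was far higher in the cold. Its sums cover all 409 models, of which 82 were tested, and are CPM of total counts without TMM scaling. They were 47.3 ± 0.827 in wild type at 25 degrees and 2030 ± 28.3 at 4 degrees, and 60.8 ± 20.4 and 1960 ± 564 in jmj4. All 82 tested models rose in wild type and 81 in jmj4, with median log2 fold changes of 6.3 and 5.46. The largest subunit gene of Rubisco there (Solyc00g500063) went from 31.4 ± 2.54 to 1440 ± 145 in wild type. Among light-harvesting and photosystem proteins, 25 of 86 rose and 5 fell in both adjustments (adjusted p = 0.000251; adjusted p = 0.93 with an estimated correlation). Of its plastid-type copies 17 of 18 rose and 0 fell (adjusted p = 8.28e-25; adjusted p = 0.0184 with an estimated correlation); of the other 68 members 8 rose and 5 fell, 6 and 3 adjusted over the list alone (adjusted p = 0.826). In jmj4 against wild type at 4 degrees, 0 of the 18 copies were higher and 1 lower, 0 and 8 adjusted over the list alone. Their median log2 fold change was -0.65 (camera adjusted p = 1.63e-07, and 0.124 with an estimated correlation). The sums over all models did not separate the genotypes at 4 degrees. They were 1590, 1689 and 2612 in the jmj4 libraries against 2004, 2025 and 2060 in wild type. The division into plastid-type copies and other members was made after the data were seen.

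**Figure D1:**
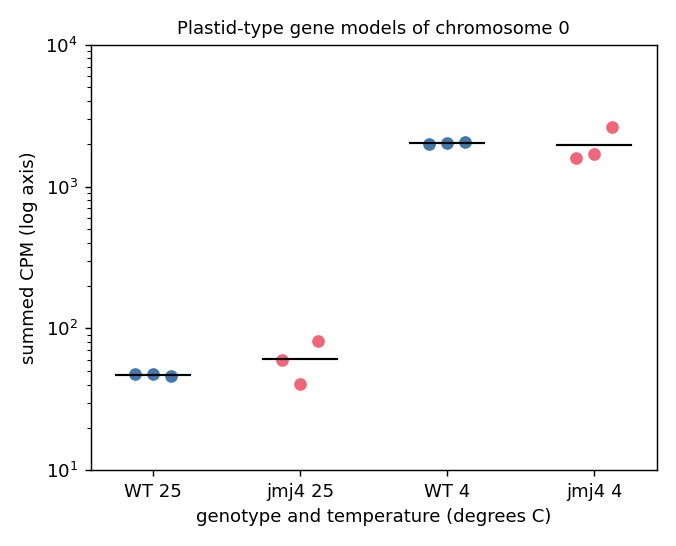
Summed level of all plastid-type gene models of chromosome 0 in each library (points, CPM without TMM scaling on a log axis) by genotype and temperature, with group means as lines. The 6 libraries at 4 degrees lie above all 6 at 25 degrees, with means of 2030 and 1960 against 47.3 and 60.8.

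Across all genes, cold changed 8721 genes in wild type (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 43.3% of those tested, of which 4475 rose and 4246 fell. At least 2-fold changes numbered 2253 and 1955. Groups did not overlap for 54.5% of genes, where chance gives 10%. The split into higher and lower depended on scaling: it was 2761 and 6310 with library size only and 3193 and 6044 with upper quartile factors, which moved the median of all genes by -0.253 and -0.179 (log2).

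Was the cold response of jmj4 alike? In the mutant 8083 genes changed, 4058 higher and 4025 lower, with 2081 and 1884 at least 2-fold; 49% of genes had groups without overlap. With library size only the split was 2852 and 4951, and with upper quartile factors 3063 and 5683, at median shifts of -0.149 and -0.155. Of the genes called, 6694 were called in both genotypes and 6691 of these moved the same way, against 1749 for independent lists. Across the 10110 genes called in either, which are not independent replicates, fold changes correlated at 0.941 with a slope of 0.915 for jmj4 on wild type. A least-squares slope is lowered by error in the wild-type fold changes, so it does not by itself show a weaker response in jmj4. Phosphatase 14B (Solyc06g062560), at 0 counts in all 25 degree libraries, reached 46.5 ± 4.81 CPM in wild type and 55.1 ± 21.3 in jmj4. The calcium-binding protein CML38 (Solyc06g073830) reached 49.9 ± 0.861 and 49.1 ± 10.4. The dehydrin ci7 (Solyc04g082200) reached 449 ± 33.3 and 348 ± 9.83, with an interaction of -0.48 (adjusted p = 0.886).

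In jmj4 the jasmonate lists rose as well: 10 of 23 synthesis genes were higher and 4 lower in both adjustments (adjusted p = 0.0225; adjusted p = 0.481 with an estimated correlation). In jasmonate signalling 11 of 17 were higher and 0 lower in both (adjusted p = 2.34e-09; adjusted p = 0.208 with an estimated correlation). In jasmonate-responsive defence 26 of 59 were higher and 6 lower in both (adjusted p = 0.0107; adjusted p = 0.77 with an estimated correlation), a call lost without jmj4 4 degree replicate 1 (0.057). WRKY factors were called (31 and 9 of 52, then 33 and 10 adjusted over the list alone; adjusted p = 2.59e-10; adjusted p = 0.337 with an estimated correlation), as were NAC factors (21 and 1 of 48 in both; adjusted p = 5.8e-08; adjusted p = 0.165 with an estimated correlation). Clock genes had 18 higher and 7 lower of 47 in both (adjusted p = 5e-05; adjusted p = 0.431 with an estimated correlation). Abscisic acid genes had 40 and 21 of 95, then 42 and 24 adjusted over the list alone (adjusted p = 0.000792; adjusted p = 0.481 with an estimated correlation), and ethylene genes 36 and 14 of 95 in both (adjusted p = 0.00111; adjusted p = 0.481 with an estimated correlation). Photosystem proteins had 25 and 6 of 86, then 24 and 6 (adjusted p = 0.00921; adjusted p = 0.93 with an estimated correlation), a call lost without jmj4 25 degree replicate 1 (0.0624). Of its plastid-type copies 17 of 18 rose in jmj4 and 0 fell in both adjustments (adjusted p = 1.8e-19; adjusted p = 0.00249 with an estimated correlation), and of the other 68 members 8 rose and 6 fell, 3 and 5 adjusted over the list alone (adjusted p = 0.811).

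At 25 degrees jmj4 leaves had higher transcript levels of several genes for defence proteins. A trypsin inhibitor-like protein (Solyc11g022590) was 97.7 ± 15.9 CPM in wild type and 364 ± 62 in jmj4 (log2 fold change 1.90, adjusted p = 9.18e-06). TOMARPIX proteinase inhibitor (Solyc11g021060) was 36.5 ± 6.59 and 90.8 ± 26.7, and proteinase inhibitors PPI3B2 (Solyc09g084490) and PPI3A2 (Solyc09g083435), which block digestive enzymes of feeding insects, were 1.79 ± 0.797 and 14.1 ± 0.963 against 10.9 ± 0.69 and 37.7 ± 3.1. PR-5x (Solyc08g080620), a pathogenesis-related protein, was 2.40 ± 1.5 against 15.4 ± 1.79. In the list of jasmonate-responsive defence proteins 6 of 59 were higher and 0 lower, 10 and 1 adjusted over the list alone (adjusted p = 8.01e-08; adjusted p = 0.337 with an estimated correlation). The gene listed beforehand as JAZ7 (Solyc11g011030, described as Pto-responsive gene 1) was 20.3 ± 0.825 in wild type and 43.2 ± 3.83 in jmj4 (adjusted p = 0.00136).

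The MADS-box transcription factor Solyc12g087830 (chromosome 12, 62892133 to 62904022) was lower in jmj4, at 31.0 ± 4.08 against 2.15 ± 0.266 CPM at 25 degrees and 28.7 ± 1.46 against 2.18 ± 1.16 at 4 degrees (log2 fold changes -3.85 and -3.69, adjusted p = 1.32e-07 and 4.3e-07). The homeobox-leucine zipper gene ROC5 (Solyc06g035940) was higher, at 43.3 ± 8.34 against 121 ± 4.5 and 47.6 ± 0.249 against 137 ± 7.18 (1.48 and 1.53, adjusted p = 4.53e-06 and 5.52e-06). Superoxide dismutase 3 (Solyc11g066390), an enzyme that removes superoxide, was lower, at 279 ± 99.2 against 102 ± 16.7 and 381 ± 99.5 against 114 ± 28.8. Ethylene response factor C.6 (Solyc03g093560), WRKY transcription factor 40 (Solyc06g068460) and the ripening regulated protein DDTFR10/A (Solyc05g052040) were lower at 25 degrees, by log2 fold changes of -1.28, -0.98 and -1.61. At 4 degrees their genotype effects were 0.29 (adjusted p = 0.737), -0.51 (0.148) and 0.32 (0.704).

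In total 183 genes differed at 25 degrees (116 higher, 67 lower in jmj4; 62 and 47 at least 2-fold), and groups did not overlap for 12.7% of genes, where chance gives 10%. The count was 100 without wild type replicate 1 and 104 without jmj4 replicate 2. The majority turned to lower without wild type replicate 3 (95 higher, 129 lower), without that library and jmj4 4 degree replicate 1 (122 and 194), and with library size only (77 and 94). Lists called at 25 degrees, besides defence proteins, were photosystem proteins (0 of 86 members past the test in both adjustments; 0.000814; adjusted p = 0.93 with an estimated correlation) and cytosolic ribosomal proteins (0 of 198 in both; 0.000123; adjusted p = 0.93 with an estimated correlation). Flavonoid synthesis (0 of 24, then 2 and 0 adjusted over the list alone; 0.00293; adjusted p = 0.717 with an estimated correlation) and antioxidant enzymes (2 higher and 1 lower of 85, then 2 and 3; 0.00372; adjusted p = 0.834 with an estimated correlation) were shifted up. Auxin response (0 higher and 1 lower of 107 in both; 0.0127; adjusted p = 0.717 with an estimated correlation) was shifted down. Each of these 5 calls was lost without single libraries. Without wild type replicate 1 the adjusted p was 0.284 for auxin response and 0.189 for ribosomal proteins, and without wild type replicate 2 it was 0.112 for auxin response and 0.13 for flavonoid synthesis. Without wild type replicate 3 it was 0.639 for photosystem proteins and 0.246 for antioxidant enzymes. Without jmj4 replicate 1 it was 0.133 for auxin response and 0.0851 for flavonoid synthesis, and without jmj4 replicate 3 it was 0.774 for photosystem proteins, 0.207 for ribosomal proteins and 0.208 for antioxidant enzymes.

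Which genes differed at 4 degrees? Of the 23 jasmonate synthesis genes tested, 4 were lower in jmj4. LOXD (Solyc03g122340) was 421 ± 71.2 CPM in wild type and 211 ± 53.5 in jmj4 (log2 fold change -1, adjusted p = 0.00399). AOC (Solyc02g085730) was 188 ± 29.1 and 103 ± 7.25 (-0.87, adjusted p = 0.000745), and OPR3 (Solyc07g007870, which reduces 12-oxophytodienoate, the next step) was 32.2 ± 4.37 and 16.5 ± 2.16 (-0.96, adjusted p = 0.000691). AOS1 (Solyc04g079730) was 228 ± 65.3 and 92.1 ± 34.5 (-1.31, adjusted p = 0.0318); its call was lost with DESeq2 and without wild type replicate 1 or 3 or jmj4 replicate 1 or 3, where adjusted p rose to 0.62. The gene listed beforehand as JAR1 (Solyc10g011660, described as an Auxin-responsive GH3 family protein) did not pass the test, at 22.6 ± 1.73 and 15.9 ± 1.15 (adjusted p = 0.0954). At 25 degrees none of these 5 genes passed, with adjusted p between 0.774 and 0.999.

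**Figure D2:**
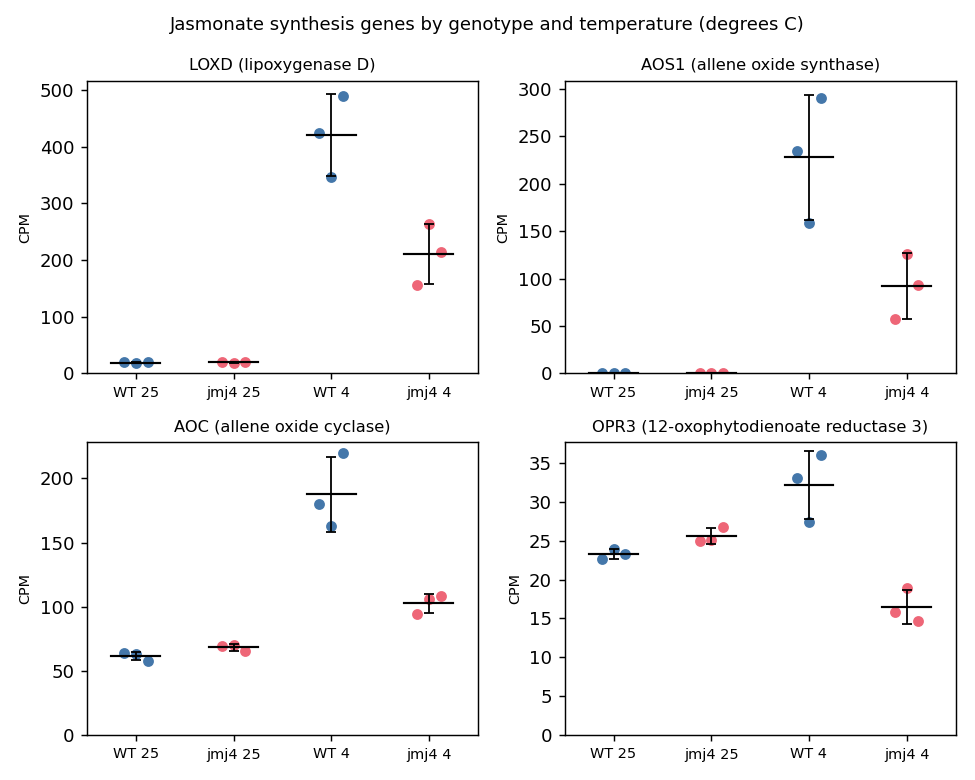
CPM of 4 jasmonate synthesis genes in each of the 12 libraries (points) by genotype and temperature in degrees C, with group means as lines and SD as bars, n = 3. At 4 degrees every jmj4 library lies below every wild-type library for LOXD, AOS1, AOC and OPR3, with means of 211, 92.1, 103 and 16.5 against 421, 228, 188 and 32.2.

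Genes of the jasmonate response followed in part. The gene listed as JAZ1 (Solyc07g042170, described as Jasmonate ZIM-domain protein 3) was 408 ± 59.5 in wild type and 259 ± 25.7 in jmj4 (adjusted p = 0.0211), and Solyc08g036620 was 4.58 ± 1.67 and 0.914 ± 0.621 (adjusted p = 0.0433). The first was lost without wild type replicate 1 or 3 or jmj4 replicate 1 or 3, where adjusted p rose to 0.18, and the second likewise, with a highest adjusted p of 0.274 over the alternatives. MYC2 (Solyc08g076930) was 241 ± 16.6 and 207 ± 31.4 (adjusted p = 0.578). In the list of jasmonate synthesis 0 of 23 members were higher and 4 lower, 2 and 5 adjusted over the list alone (adjusted p = 0.0163; adjusted p = 0.481 with an estimated correlation). That call was lost without jmj4 replicate 1 (0.0648) and with limma's rotation test, fry (0.0628), and the median log2 fold change of the list was -0.17. In jasmonate signalling 0 of 17 were higher and 2 lower, 0 and 7 adjusted over the list alone (adjusted p = 1.78e-05; adjusted p = 0.343 with an estimated correlation). Defence proteins again had more higher members, 4 against 1 of 59, then 8 and 2 (adjusted p = 0.0384; adjusted p = 0.839 with an estimated correlation), a call lost without wild type replicate 1 or 2 (0.125 and 0.213) or jmj4 replicate 1 or 3 (0.656 and 0.368). Proteinase inhibitor type-2 (Solyc03g020030) was 6.76 ± 0.712 in wild type and 20.3 ± 3.87 in jmj4 (adjusted p = 0.00377).

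CBF1 (Solyc03g026280) was 9.24 ± 1.76 CPM in wild type and 3.61 ± 0.962 in jmj4 (log2 fold change -1.36, adjusted p = 0.0118), a call lost without wild type replicate 3 or jmj4 replicate 1, where adjusted p rose to 0.104. In CBF and DREB factors 0 of 10 were higher and 1 lower, 0 and 4 adjusted over the list alone (adjusted p = 0.000139; adjusted p = 0.225 with an estimated correlation). The 2 genes Solyc08g007820 and Solyc08g007830, described as Dehydration-responsive element-binding protein 1E, were 12.5 ± 4.4 and 5.70 ± 2.1 in wild type against 5.93 ± 1.56 and 1.66 ± 0.601, without passing the test (adjusted p = 0.0607 and 0.0523). The programmed cell death protein 4-like gene (Solyc03g111640; chromosome 3, 56678857 to 56685630) was 218 ± 18.4 in wild type and 26.5 ± 4.34 in jmj4 (-3.04, adjusted p = 5.9e-09). Tryptophan synthase beta chain (Solyc10g005320), the last enzyme of tryptophan synthesis, was 55.2 ± 5.04 and 9.09 ± 3.7 (-2.59, adjusted p = 1.86e-05), a cytochrome P450 (Solyc03g111290) 11.4 ± 2.45 and 2.18 ± 0.367 (-2.38, adjusted p = 0.000102), and Ethylene Response Factor D.3 (Solyc01g108240) 17.2 ± 4.33 and 4.19 ± 1.07 (-2.04, adjusted p = 0.00517). The last was lost without wild type replicate 3, where adjusted p rose to 0.0649. Serine decarboxylase (Solyc08g066260) and PR-5x (Solyc08g080620) were higher, at 5.21 ± 0.234 against 22.7 ± 5.62 and 1.86 ± 0.877 against 11.1 ± 3.46.

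In total 207 genes differed at 4 degrees, 74 higher and 133 lower in jmj4, with 40 and 72 at least 2-fold; groups did not overlap for 16.6% of genes, where chance gives 10%. The count was 107 without wild type replicate 1, 74 without wild type replicate 3, 124 without jmj4 replicate 1 and 106 without jmj4 replicate 3; without jmj4 replicate 1 and wild type 25 degree replicate 3 the split was 117 and 121. Of the 317 genes called at either temperature 73 were called at both and 72 of these went the same way, 44 higher and 28 lower in jmj4, where independent lists would share 0.87. Their fold changes at the 2 temperatures correlated at 0.894 across these 317 genes, which are not independent replicates. Other lists called at 4 degrees were flavonoid synthesis (1 higher and 0 lower of 24, then 3 and 0 adjusted over the list alone; adjusted p = 1.21e-05; adjusted p = 0.431 with an estimated correlation) and cytosolic ribosomal proteins (0 of 198 in both; 0.00228; adjusted p = 0.93 with an estimated correlation). Core histones (0 of 56, then 1 and 0; 0.0161; adjusted p = 0.93 with an estimated correlation) and salicylic acid and pathogenesis-related genes (1 and 0 of 69, then 4 and 0; 0.00825; adjusted p = 0.343 with an estimated correlation) were shifted up. The salicylic acid list also took LPR1, CPR1, XPR1 and ZPR1 genes by name; its other 61 members gave 1 and 0, then 4 and 0 (adjusted p = 0.00864; adjusted p = 0.319 with an estimated correlation). Ethylene genes (1 and 3 of 95, then 1 and 5; 0.0225; adjusted p = 0.717 with an estimated correlation) were shifted down. Flavonoid synthesis kept its call without each single library of the comparison, but not with fry (adjusted p = 0.119). Jasmonate signalling and CBF and DREB factors kept theirs without each single library and with fry (adjusted p = 0.0196 and 0.0087). Ribosomal proteins, core histones, salicylic acid and ethylene genes lost theirs without some libraries. Without wild type replicate 1 the adjusted p was 0.0726 for ethylene genes and 0.0579 for salicylic acid genes. Without wild type replicate 3 it was 0.0533 for salicylic acid genes, 0.252 for core histones and 0.0881 for ribosomal proteins. Without jmj4 replicate 1 it was 0.173, 0.103 and 0.0739 for ethylene, salicylic acid and ribosomal proteins, and core histones turned to the other direction (0.892). Without jmj4 replicate 3 ribosomal proteins had 0.203.

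**Figure D3:**
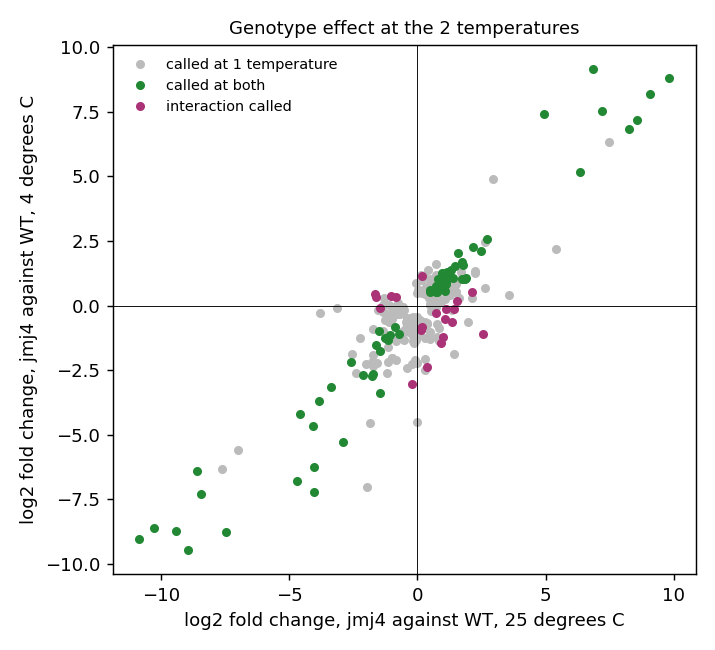
Log2 fold change of jmj4 against wild type at 25 degrees (x axis) and at 4 degrees (y axis) for the 317 genes called at either temperature, with colours for genes called at both and genes with an interaction call. Genes called at both temperatures lie near the diagonal, 72 of 73 with the same sign; values beyond about 5 belong to genes near 0 counts in 1 genotype, whose fitted fold change is no bound.

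Did the cold response itself differ between genotypes? In all 21 genes did, 6 with a positive and 15 with a negative interaction (942 at an unadjusted p under 0.05). The split depended on 2 libraries: it was 15 and 16 without wild type 25 degree replicate 3, 17 and 15 without jmj4 4 degree replicate 1, and 55 and 24 without both. Of the 21 genes, 13 rose in wild type and had a smaller positive fold change in jmj4, 3 had a larger one, and 5 had fold changes of opposite sign in the genotypes. The programmed cell death protein 4-like gene (Solyc03g111640) rose in wild type from 48.0 ± 6.34 to 218 ± 18.4 CPM and fell in jmj4 from 41.2 ± 3.79 to 26.5 ± 4.34 (interaction -2.81, adjusted p = 1.73e-06). AOC (Solyc02g085730) and OPR3 (Solyc07g007870) had interactions of -1.03 and -1.10, each with adjusted p = 0.0158; OPR3 rose in wild type (0.47, adjusted p = 0.00514) and fell in jmj4 (-0.64), and the rise lost its call with library size only and upper quartile scaling, where adjusted p reached 0.224. For LOXD (Solyc03g122340) and AOS1 (Solyc04g079730) the interaction did not pass the test, at -1.03 (adjusted p = 0.196) and -1.81 (adjusted p = 1). A gene described as cytosine-5 DNA methyltransferaseL1 (Solyc10g078190), an enzyme that methylates DNA, rose in wild type from 3.63 ± 0.562 to 20 ± 5.43 and was 7.05 ± 1.73 and 7.33 ± 0.414 in jmj4 (-2.39, adjusted p = 0.00403). Alcohol acyl transferase (Solyc05g015800) and ABC transporter G family member 11 (Solyc01g105450) had interactions of -1.98 and -1.27 (adjusted p = 0.00403 and 0.00696).

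Among lists, jasmonate synthesis had 0 members with a positive and 2 with a negative interaction of 23, 0 and 3 adjusted over the list alone (adjusted p = 0.00111; adjusted p = 0.343 with an estimated correlation). Jasmonate signalling had 0 of 17 past the test, 0 and 3 adjusted over the list alone (adjusted p = 3.27e-05; adjusted p = 0.343 with an estimated correlation), and photosystem proteins 0 of 86, then 0 and 2 (adjusted p = 0.00262; adjusted p = 0.93 with an estimated correlation). The last was lost without wild type 25 degree replicate 3, jmj4 25 degree replicate 3 or jmj4 4 degree replicate 1 (0.744, 0.817 and 0.777), and its plastid-type copies alone gave adjusted p = 0.000511 (adjusted p = 0.302 with an estimated correlation) against 0.058 for the other members. With fry 0 of these 3 lists passed, at 0.0691, 0.0685 and 0.673 in the order named. The interaction count depended on single libraries. It was 11, 12, 8 and 9 without wild type 25 degree replicates 1 and 2 and wild type 4 degree replicates 1 and 3, in that order; 11, 8 and 13 without jmj4 25 degree replicates 1, 2 and 3; and 32 without jmj4 4 degree replicate 1. The interaction calls of AOC and OPR3 were both lost with library size only and without wild type 25 degree replicate 1, jmj4 25 degree replicate 1 or 2, or wild type 4 degree replicate 1 or 3. That of OPR3 was also lost without jmj4 25 degree replicate 3 or jmj4 4 degree replicate 3. The highest adjusted p was 0.0824 for AOC and 0.0996 for OPR3.

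**Figure D4:**
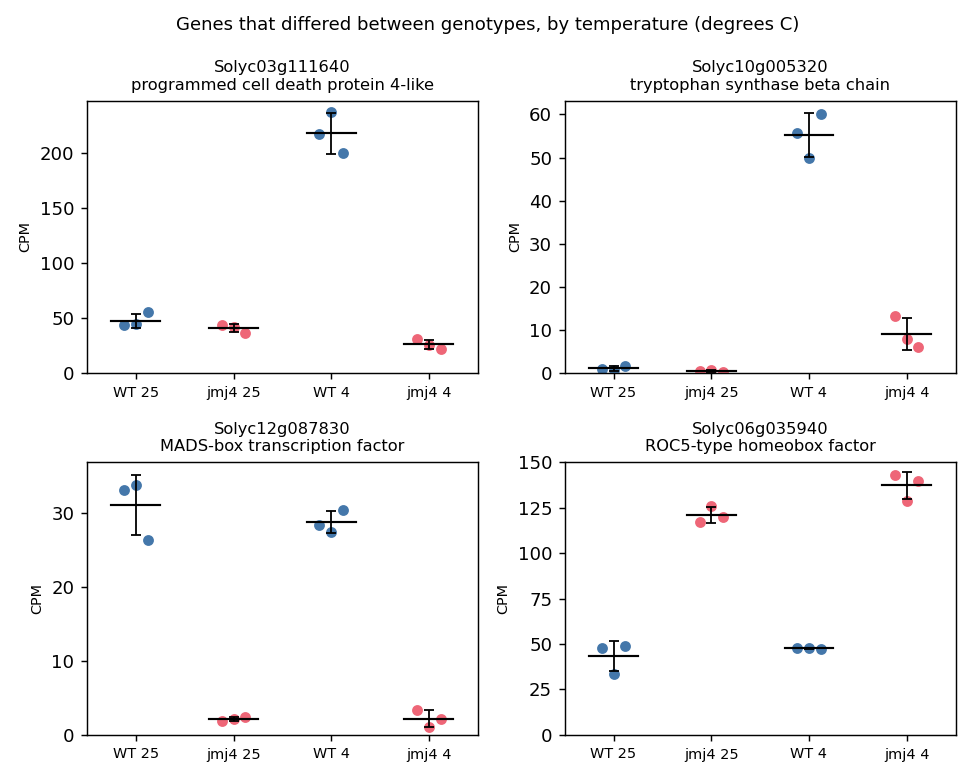
CPM of 4 genes in each of the 12 libraries (points) by genotype and temperature in degrees C, with group means as lines and SD as bars, n = 3. The programmed cell death protein 4-like gene and tryptophan synthase beta chain differ at 4 degrees (218 against 26.5 and 55.2 against 9.09), the MADS-box and ROC5-type genes at both temperatures.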

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

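The tests of the jasmonate genes, of neighbouring on and off genes and of the plastid-type models were chosen after the results were seen. Counts over other splits of the libraries and over relabellings for on and off genes were planned.

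A difference in cold response between genotypes, tested as an interaction, singled out 21 genes. Of these, 5 kept the call in all 22 alternatives run for single genes (Solyc03g111640, Solyc03g111290, Solyc10g078190, Solyc05g015800 and Solyc01g105450) and 16 lost it in at least 1. The replicate block ended the calls of Solyc03g093550 (12 alternatives in all) and Solyc06g083900 (17). The rise in the cold was smaller in jmj4 for the Rossmann-fold gene Solyc10g078360 (-3.65), the cytochrome P450 Solyc03g111290 (-2.75), the DNA methyltransferase gene Solyc10g078190 (-2.39) and ARGINASE 2, Solyc01g091170 (-2.22). It was also smaller for the alcohol acyl transferase Solyc05g015800 (-1.98), the IAA-amino acid hydrolase Solyc05g006220 (-1.59), the acetylornithine deacetylase Solyc08g076970 (-1.58), the proteinase inhibitor Solyc09g083435 (-1.55), the alcohol dehydrogenase Solyc12g096780 (-1.36) and the ABC transporter Solyc01g105450 (-1.27). The MYB factor Solyc06g083900 (-1.04), AOC, Solyc02g085730 (-1.03), and the GDSL lipase Solyc02g071620 (-1.02) followed. The rise was larger in jmj4 for the PDDEXK-like gene Solyc02g078150 (2.12), DDTFR10/A, Solyc05g052040 (1.92), and the serine decarboxylase Solyc08g068600 (1.34). For some of these genes the genotypes differed at 25 and not at 4 degrees. Solyc08g076970 was higher in jmj4 at 25 degrees (log2 fold change 2.12, edgeR adjusted p = 4.32e-06) and not at 4 degrees (0.54, adjusted p = 0.18). Solyc12g096780 (1.54 and 0.17) and Solyc01g105450 (1.12 and -0.14) were alike, and Solyc02g078150 was lower at 25 degrees only (-1.66 and 0.46). AOC differed at 4 degrees only. A smaller rise is thus not always a lower level in the cold. The programmed cell death protein 4-like gene Solyc03g111640 (-2.81) and OPR3, Solyc07g007870 (-1.10), rose in wild type and fell in jmj4, though the rise of OPR3 lost its call in 2 scalings. The stem-specific TSJT1 gene Solyc03g006490 (1.40) fell in wild type (-0.89) and rose in jmj4 (0.51), a rise that lost its call in 6 alternatives. The ethylene-responsive factor Solyc03g093550 (1.15) and the sarcosine oxidase Solyc08g006430 (0.93) did not pass in wild type (-0.04 and -0.25) and rose in jmj4 (1.11 and 0.68). Lists with an interaction were jasmonate biosynthesis (adjusted p = 0.00111), jasmonate signalling (3.27e-05) and photosystem proteins (0.00262), none of which held with an estimated correlation (0.343, 0.343 and 0.93).

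For the 4 two-group comparisons, 10 splits of 6 libraries are too few for a share under 0.05. Only the real split, 1 of 10 each time, gave as many genes: 8721 against a highest other count of 0 for cold in wild type, 8083 against 0 for cold in jmj4, 183 against 1 at 25 degrees and 207 against 0 at 4 degrees. For the interaction 4 of 100 relabellings, the real one included, gave at least 21 genes. The 100 were drawn from a larger set, so this share is itself uncertain. Relabelling within a temperature also moves genotype effects shared by both temperatures into the spread within groups, which can lower the other counts. The share therefore cannot decide whether chance accounts for the 21 genes. The highest other count, 388, came from swapping the genotype labels at 4 degrees, which adds up the genotype effects shared by both temperatures. That count thus reflects genotype itself and is not a draw free of its effects, though it is 1 of the 4.

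LOXD, AOS1, AOC and OPR3 were lower in jmj4 than in wild type at 4 degrees, with a median log2 fold change of -0.98. It was -0.87 without jmj4 4 degree replicate 1, so the difference of these genes did not rest on that library alone. They were picked by their calls in these data, so the remaining size may be overstated. The camera call of the whole synthesis list was lost without that library (adjusted p = 0.0648). For a general weakening of the cold response, 6 synthesis genes were used (these 4, AOS2 and JAR1). They were named before the data were examined but taken for this test after their median was seen. Observed minus predicted interaction, from the slope of all cold genes, had a median of -0.77 (-1.06 to -0.32). The median was -0.94 over the 4, which were picked by their calls, and -0.13 over all 23 genes of the list. The named genes fell below the prediction, while the list as a whole hardly did. Since the 4 picked genes make up most of the 6, the test cannot decide on a general weakening. The gap between the 4 genes and the median of all other genes was -0.97 or lower under each scaling. Scaling moves all genes of a library alike and cancels in such a gap, and the 4 genes were picked by their calls. The gap is therefore no test of scaling. It shows only that these genes lay below most others whichever scaling was used. Their median fold change was -0.98 with RLE and library size only and -0.95 with upper quartile factors. An effect of the genotype is a hypothesis that remains open, and it cannot be separated from differences in background or growth between the lines, which were not tested.

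At both temperatures 16 entries were on in 1 genotype and at no more than 3 counts over the other genotype's 6 libraries, 8 of them on in jmj4. A flavin-containing monooxygenase (Solyc01g033995) was at least 132-fold higher in jmj4 at 25 degrees and at least 47.3-fold at 4 degrees, and F-box gene Solyc08g074895 was at least 166-fold and 43.7-fold lower, with a floor of 3 counts over the group. Random calls among low counts were argued against, since 1 of 200 relabellings, the real one, gave 16 such entries and the highest other gave 1. Neighbouring pairs within 100 kb numbered 3, where 10000 random sets gave a mean of 0.085 and a 95th percentile of 1. The pairs were close models on the same strand. Solyc01g033995 and Solyc01g034010 lay at 33081083 to 33084723 and 33084813 to 33086248 of chromosome 1. Solyc08g074895 and Solyc08g074910, with the same F-box description, lay at 57163901 to 57167012 and 57167757 to 57170251 of chromosome 8. Solyc05g043390 (U-box domain-containing protein 35) and Solyc05g043405 (Unknown protein) lay at 55572933 to 55573637 and 55582092 to 55584323 of chromosome 5. The descriptions of that pair differed. Random sets do not allow for adjacent models that share reads or a description. The pair on chromosome 5 alone would not exceed the 95th percentile of 1. The count therefore cannot decide on stretches of different genetic background in the lines. An effect of the mutation on neighbouring genes stays open.

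Plastid-type gene models of chromosome 0 were higher at 4 degrees in both genotypes. In summed CPM without TMM scaling, the lowest library at 4 degrees held 19.5 times the highest at 25 degrees. Plastid RNA carried over at fixed proportions from 1 source cannot be told apart from other sources. The lowest correlation between 2 libraries at 4 degrees was 0.853, under the 0.963 of the lowest of 1000 simulations with counting error alone, but wild-type libraries of 1 group also correlated as low as 0.92, so the spread between libraries may account for it. An effect of cold on plastid transcripts, or on how they were captured, stays open and was not tested.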

How the results depend on the processing

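Leaving out both libraries lowest on the third component, leaving out the plastid-type models and the narrowed lists were chosen after seeing the data; the other alternatives were fixed before. Of 245 called values of named genes, 0 changed direction under the alternatives run for single genes, which were all but the fold minimum and only the groups compared. The stricter filter covered 242 of them and the analysis without plastid-type models 243. Leaving out single libraries ended the call of 42, library size only of 19, limma-voom of 17, upper quartile factors of 8, both libraries left out of 4, the replicate block and the stricter filter of 3 each, RLE of 2, and DESeq2 and no filter of 1 each. The cause was not tested.

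The interaction count of 21 was 35 with no low-count filter, 58 with DESeq2, 8 with limma-voom, 5 with a fold minimum of 1.5 and 79 with both libraries left out; all 21 genes were among those of DESeq2 and among those with both libraries left out. For jmj4 at 4 degrees the count of 207 was 332 with DESeq2, which shared 205, 325 with only the groups compared and 47 with the fold minimum. For jmj4 at 25 degrees the count of 183 was 106 with only the groups compared, 57 with the fold minimum and 316 with both libraries left out, which shared 162. The fold minimum left 3971 genes for cold in wild type and 3720 in jmj4. A fold minimum is a stricter test by construction; the cause of the other shifts was not tested.

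Without single libraries the counts ranged from 7225 to 8248 for cold in wild type, 6921 to 7567 for cold in jmj4, 100 to 224 for jmj4 at 25 degrees, 74 to 163 at 4 degrees and 8 to 32 for the interaction. Leaving out a library leaves fewer samples.

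Of 155 list tests 36 passed, 28 up and 8 down, and 0 passed with an estimated correlation. With fry 37 passed, of which 20 were shared: 16 calls ended, 15 of them in the genotype and interaction tests, and 17 arose, all in the cold comparisons, such as guard cell markers in wild type (0.00104). Fry asks whether members move one way on balance, not whether they differ from other genes. Between 33 and 41 passed without single libraries. Core histones turned direction in several settings: at 25 degrees, where they had no call (0.77), the adjusted p was 0.00842 without wild type replicate 2 (range 1.68e-07 to 0.976), and at 4 degrees 0.892 without jmj4 replicate 1 (range 1.76e-06 to 0.892) and 0.775 with both libraries left out. Their interaction, without a call (0.0922), had 0.0259 without wild type 25 degree replicate 3 (range 6.04e-07 to 0.774) and 1.01e-07 with both left out, and that of photosystem proteins turned at 0.047 with both left out. The cause was not tested.

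Replicate numbers did not pair the libraries: 3 of 18 same-number pairs had deviations correlating above 0.1 (-0.251 to 0.26), and 3 of 12 libraries correlated best with their own number. With the number as a block the counts were 8631, 8031, 173, 186 and 22 (and the calls of Solyc08g036620 at 4 degrees and of Solyc03g093550 and Solyc06g083900 in the interaction ended), in the order cold in wild type, cold in jmj4, jmj4 at 25 and 4 degrees, and interaction. Leaving out organelle chromosomes was not run, since the table has none under such names.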

Other observations

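The group of sterol enzymes and its test were chosen after the calls at 25 degrees were seen. Of 21 genes described as sterol enzymes, 6 were higher and 1 lower in jmj4 at 25 degrees, 9 and 1 adjusted over the list alone (adjusted p = 1.35e-07; adjusted p = 0.0378 with an estimated correlation). Those calls picked the group, so these p-values are no independent support. At 4 degrees 1 was higher and 1 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0257, and 0.302 with an estimated correlation). The interaction was shifted down (camera adjusted p = 0.0321, and 0.319 with an estimated correlation). In it 0 members passed, 1 up and 1 down adjusted over the list alone. Delta(24)-sterol reductase (Solyc02g069490) was 437 ± 51 CPM in wild type and 719 ± 26.9 in jmj4, and 7-dehydrocholesterol reductase (Solyc06g074090) 79.8 ± 11 and 134 ± 6.64. The first lost its call without wild type replicate 1, where adjusted p was 0.0525. A hypothesis of a rise across all such genes was tested on the 14 members without a call, and it was not decided. Their median log2 fold change was 0.08, but they were kept for having no call, so a low median is partly built in and does not weigh against a shared rise, while limma's rotation test (fry) over those 14 genes gave 0.000132. A shared rise cannot be told apart from a rise of some members.

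Positions of some named genes were compared. The programmed cell death protein 4-like gene (Solyc03g111640) lay 45 kb from Solyc03g111590, a member of the JmjC list with no genotype call, and 360.7 kb from the cytochrome P450 gene Solyc03g111290. Solyc10g078190 and Solyc10g078360 lay 138.8 kb apart. These pairs were noticed after the values were seen, and their number was not tested against chance.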
